A study of Homo sapiens with 8 samples.

How the data were processed

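RNA of single nuclei from frozen human lumbar spinal cord was read for 7 donors, with 10x Chromium 3' v3 chemistry per the labels' protocols. All samples are of 1 group, so comparisons were made between cell classes of the same donors. The deposited matrix holds raw UMI counts, which the authors left without normalization, for 22238 genes and 55289 nuclei. Reads were aligned and counted with Cell Ranger 3.0.2 on build hg38, per the submitters' processing notes. The authors kept nuclei that passed their quality filter. Treatment of doublets and of ambient RNA, and the way the classes were drawn, are not given in the sources used here. The deposited table per nucleus gives UMI and gene counts, the mitochondrial share in percent as computed by the authors, and other columns with the authors' annotation of donor, class and subtype (11 classes, 64 subtypes, 35 of them neuronal). No column of values per sample was left unused.

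Every value was checked to be a whole number of at least 0, and column sums and gene numbers equalled the deposited ones in all nuclei. No mitochondrial gene stands among the genes of the matrix, while the percent column reaches 4.99, so that column was read as computed before their removal. Nuclei held 1001 to 119899 UMIs (median 3931) and a median of 2000.0 genes, and 1994 genes held no UMI. Donors 1 to 7 held 6335, 7324, 6704, 15048, 5155, 8354 and 6369 nuclei, with 36563510, 37527406, 48996150, 71543996, 17627531, 39512271 and 32118728 UMIs. Of 8 labelled samples, that titled 6A matched no nucleus, and barcodes of donor 4 came from 2 libraries, 4A and 4B, which were summed as donor 4. Whether the numbers 4 and 6 of the nuclei are those of the sample titles was left open, and no comparison depends on it. Barcodes of both sides of a comparison come from the same tissue of the same donor, which is where the pairing comes from, so donor entered every fit as a block. XIST, TSIX and Y-linked genes, 90 in all, were left out of tests.

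Counts were summed per donor and class over at least 10 nuclei (3 for motoneurons). Sums were filtered with filterByExpr, scaled with TMM and fitted with glmQLFit and glmQLFTest of edgeR 4.0.16, and p was adjusted by Benjamini-Hochberg with 0.05 as the threshold. The SE of a log2 fold change is its absolute value divided by the square root of the test's F statistic, not a spread over donors. Dorsal neurons were compared with mid and ventral ones with donor and transmitter class in the model, and motoneurons with all other neurons. The 2 subtypes with most nuclei were compared for oligodendrocytes, microglia and astrocytes. Neurons were compared with the mean of the other classes in 1 fit over classes with at least 4 donors, read only through gene lists because class-defining genes are circular. UMIs per nucleus and transmitter shares were tested by exact sign-flip permutation of donor differences. Levels in CPM are means over donors of summed counts unless called pooled, where the counts of all donors were summed first, and those with an SD beside a fold change use TMM-scaled library sizes. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with version 1.17.8 of the R package data.table.

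The comparisons, 25 functional gene lists and 14 marker lists were written before the data were examined. The lists came from general knowledge of the cord and of motoneuron disease, which can include published accounts of such samples, so a list's direction is not independent evidence. The functional lists were cytoskeleton of large neurons, ALS genes, spastic paraplegia genes, myelin, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, chaperones, immediate early genes, homeostatic and activated microglia genes, and reactive and perisynaptic astrocyte genes. They also covered neuropeptides, analgesic and nociceptive receptors, ionotropic glutamate receptors, GABA and glycine receptors, sodium, potassium and calcium channels, HOX genes, and transcription factors of the dorsal horn, ventral cord, local circuits and long-range projections. Lists were tested with camera of limma at a preset correlation of 0.01. With an estimated correlation camera allows for genes that move together across samples, and then asks whether the list moved more than other genes. The test fry asks only whether the list itself moved, so a list may pass it when most genes move. Counts of genes past the threshold over the list alone were adjusted within the list.

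Genes named in the text followed a rule: up to 8 genes per direction with the largest log2 fold change among those that passed, in the upper range of expression and with the same sign in every donor, and up to 4 per list with the smallest adjusted p. Clone-based symbols were left out. Some genes that met the rule are not reported here. Others, such as NEFM, SLC5A7, SNAP25, C9orf72, SOD1, TUBA4A, STMN2, OPRM1 and SLC17A6, are list members or markers chosen after their values were seen, as were all genes named for whole classes. GENCODE v29, whose release may differ from the authors' annotation, gave positions on GRCh38 for 22183 of the symbols: NEFL lies on chromosome 8 at 24950955 to 24957110, NEFH on 22 at 29480230 to 29491390, PRPH on 12 at 49293252 to 49298686, GAD1 on 2 at 170813213 to 170861151, and CD163 on 12 at 7470813 to 7503893. Reads of near-identical copies, such as ribosomal proteins and their pseudogenes, tubulins, HSPA1A and HSPA1B, or ACTB, may be assigned in part to another copy or lost.

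The pipeline was tested on simulated data with the depth and donor spread of each comparison and 200 changed genes, 100 at each fold. At 2-fold and 4-fold it recovered 13 and 85% for motoneurons (10430 genes), 99 and 93% for excitatory against inhibitory neurons (11618), 90 and 90% for dorsal neurons (9794), 96 and 94% for oligodendrocytes (12156), 90 and 94% for microglia (10153), 90 and 88% for astrocytes (11636), and 87 and 92% for classes (13452). Unchanged genes called numbered 5, 8, 6, 6, 7, 9 and 20. The changed list, of genes raised 2-fold, was found in every simulation and 0 of 20 unchanged lists were called. Simulated genes varied independently, so this does not show how often lists are wrongly called where genes move together. Motoneuron fold changes near 2-fold would thus mostly be missed.

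The alternatives were median-of-ratios scaling, DESeq2, no low-count filter, no donor block, each donor left out, larger minima (20 nuclei, 5 for motoneurons), and equal numbers of nuclei thinned to 1000.0 UMIs for motoneurons and 2000.0 for the others. Further ones were library 4A or 4B left out or taken as its own replicate, other definitions of the compared classes, pooled shares, mean UMIs, genes detected, and an estimated correlation or fry for lists. Motoneuron barcodes were also split by UMIs at 2500 and 10000.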

Results

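Oligodendrocytes, which wrap axons in myelin, made up most nuclei of the lumbar cord: 55.8 ± 3.01% (mean ± SD, n = 7 donors) of 55289 nuclei. Microglia, the resident immune cells, followed with 17.7 ± 2.33%, and astrocytes, which clear transmitter and buffer potassium, with 12.3 ± 3.75%. Neurons made up 5.93 ± 2.97% (3153 nuclei, 1331 of them called motoneurons, 2.80 to 10.6% by donor) and oligodendrocyte precursors (OPC) 4.34 ± 0.612%. Meningeal cells held 1.79 ± 2.33%, endothelial cells 0.838 ± 0.386%, lymphocytes 0.402 ± 0.264%, Schwann cells 0.378 ± 0.521%, pericytes 0.250 ± 0.135% and ependymal cells 0.244 ± 0.114%. Without donor 6 the mean meningeal share was 0.929% and the mean Schwann cell share 0.188%. The chi-square of class by donor was 3208 with 60 degrees of freedom (Cramér's V 0.0983), a description only, since nuclei of 1 donor are not replicates. Shares sum to 100% within a donor, so a low share of 1 class can follow from a high share of another.

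**Figure D1:**
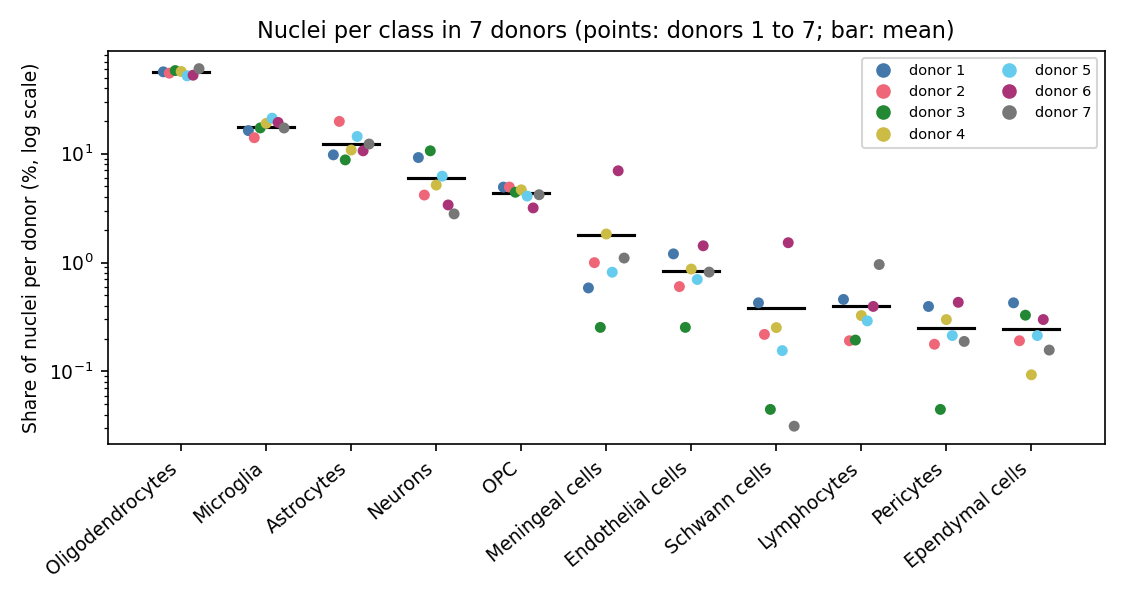
Share of nuclei (%, log axis) in each of 11 cell classes; points are donors 1 to 7 and bars are means. Oligodendrocytes held 55.8% on average, and the meningeal share ranged from 0.254 to 6.96%.

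Known markers were highest in their own class for all 9 oligodendrocyte, 7 lymphocyte, 6 endothelial, 5 pericyte, 6 meningeal, 6 Schwann cell and 6 ependymal genes. Neurons were highest for 8 of 9 markers, OPC for 6 of 7, microglia for 6 of 7 and astrocytes for 5 of 7. SLC1A3, a glutamate transporter listed for astrocytes, stood at 2330 CPM (counts scaled to equal library size) in microglia and 1151 in astrocytes. ADGRV1 stood at 647 CPM in ependymal cells against 19.5 in astrocytes, PTPRC at 2121 CPM in lymphocytes against 999.7 in microglia, CSPG4 at 109 CPM in pericytes against 89.7 in OPC, and NRXN3 at 2629 CPM in Schwann cells against 2620 in neurons. If the authors named the classes from such genes, these matches are circular.

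Neurons other than motoneurons held the most RNA, with a median of 16840 ± 4908 UMIs per nucleus (mean of donor medians ± SD, n = 7). Nuclei called motoneurons held 1392 ± 205 UMIs, the fewest of all groups, although motoneurons are the largest neurons of the cord. The difference was -3.55 ± 0.54 log2 units (SD), an 11.7-fold lower median, and no donor went the other way (exact p = 0.0156, the smallest possible, adjusted p = 0.172 over 11 comparisons). OPC held 5797 ± 1435 UMIs, ependymal cells 5572 ± 1876, astrocytes 5467 ± 2548, endothelial cells 5082 ± 752, meningeal cells 4497 ± 622, pericytes 4189 ± 781 (n = 6) and oligodendrocytes 4121 ± 918. Microglia held 2960 ± 851, Schwann cells 2410 ± 331 (n = 4) and lymphocytes 1846 ± 352. Neurons as a whole exceeded lymphocytes by 1.67 ± 1.41 log2 units (SD, exact p = 0.0313, adjusted p = 0.172) and microglia by 1.02 ± 1.34 (exact p = 0.0781, adjusted p = 0.286). None of the 11 differences passed adjustment. With 7 donors a single difference at the smallest possible exact p cannot pass over 11 comparisons. Schwann cells, with 4 donors and a smallest possible exact p of 0.125, could not pass at all. Neurons as a whole include the nuclei called motoneurons, and their donor medians ran from 1956 to 17020 UMIs. Other neurons ran from 10810 to 24700, above the highest donor median of any non-neuronal class (10600, astrocytes), and were not tested against those classes. Mean UMIs in place of medians gave -2.84 for motoneurons minus other neurons (adjusted exact p = 0.0246), and 9 of the 11 differences then passed.

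**Figure D2:**
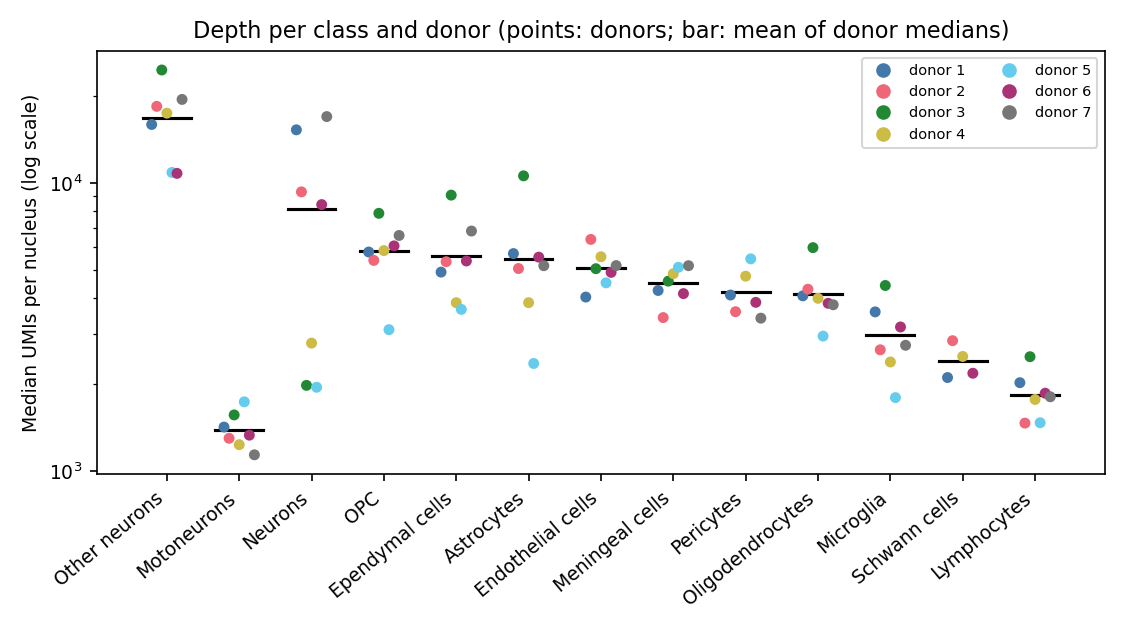
Median UMIs per nucleus (log axis) by class; points are donors with at least 10 nuclei and bars are means of donor medians. Motoneurons stood at 1392 UMIs and other neurons at 16840.

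Excitatory neurons, which release glutamate, outnumbered inhibitory ones, which release GABA or glycine, in 6 of 7 donors: 32.7 ± 10.9% against 26.9 ± 12.7% of neurons (mean ± SD). The difference was 5.79 ± 3.76 points (exact p = 0.0313, a single test). With motoneurons left out of the total the shares were 54.2 ± 6.29% and 41.8 ± 5.23%, a difference of 12.4 ± 11.1 points (exact p = 0.0313). Leaving 1 donor out gave 4.72 to 6.85 points, with an exact p of 0.0313 without donor 7 and 0.0625 in the other 6 runs. Dorsal excitatory subtypes held 631 nuclei in 12 subtypes, mid ones 230 in 4 and ventral ones 111 in 3. Dorsal inhibitory subtypes held 471 nuclei in 9 subtypes, mid ones 88 in 2 and ventral ones 224 in 3. Nuclei called motoneurons made up 37.7 ± 24.5% of neurons, from 9.26 to 71.0% by donor. Of these 1331 barcodes 1170 held at most 2500 UMIs, so the share counts barcodes as annotated and not motoneurons of the tissue.

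Neurons as a class differed from the mean of the other classes in 264 of 316 list genes (190 higher, 74 lower, adjusted p < 0.05 over 14663 genes, n = 7). All 15 GABA and glycine receptor genes were higher (median log2 difference 4.74, adjusted p = 0.00128 with an estimated correlation), as were all 16 ionotropic glutamate receptors (3.45, 0.000161), 10 calcium channels (4.42, 0.0000824), 18 potassium channels (3.18, 0.000137) and 9 sodium channels (3.82, 0.00664). All 13 neuropeptides (4.83, 0.00906) and 16 analgesic and nociceptive receptors (4.12, 0.00345) were also higher. The cytoskeleton list was higher in 18 of 19 genes (2.87, 0.0303), dorsal horn transcription factors in 9 of 11 with 1 lower (0.00135), and spastic paraplegia genes in 9 of 14 with 3 lower (0.0214). KIF5A, a kinesin of axonal transport, was higher by 3.99 ± 0.15 (SE).

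Some glial lists and the ribosomal proteins were lower in neurons. Perisynaptic astrocyte genes split (6 higher and 5 lower of 12), and 4 of 9 homeostatic microglia genes were lower without a list call (adjusted p = 0.0961). All 11 myelin genes were lower (adjusted p = 0.0000261, adjusted p = 0.126 with an estimated correlation), as were 17 of 19 cytosolic ribosomal protein genes (0.000129, or 0.344 with an estimated correlation) and 9 of 10 reactive astrocyte genes (0.0116 with an estimated correlation). Of 15 activated microglia genes 7 were lower and 1 higher (adjusted p = 0.00311, or 0.173 with an estimated correlation), and 4 of 5 local circuit transcription factors were lower (0.00535, or 0.109 with an estimated correlation). The 31 ALS genes gave 17 higher and 6 lower, a mixed set that did not pass as a list (adjusted p = 0.317, or 0.507 with an estimated correlation). SOD1 was higher by 1.15 ± 0.17 (SE), TUBA4A by 2.87 ± 0.22 and C9orf72 by 0.50 ± 0.12, while PFN1 was lower (-1.16 ± 0.21). All 5 lumbar HOX genes, which set position along the body axis, were higher in neurons; the list did not pass (adjusted p = 0.294, or 0.416 with an estimated correlation). Oxidative phosphorylation was higher in 13 of 15 genes and the list did not pass (adjusted p = 0.123, or 0.607 with an estimated correlation). With the nuclei called motoneurons left out, 259 list genes passed and 16 of 19 cytoskeleton genes were higher and 1 lower, with a median of 1.52. Oxidative phosphorylation was then higher in 9 of 15 genes and lower in 0 (median 0.36), and the 31 ALS genes gave 14 higher and 6 lower.

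Nuclei called motoneurons carried more RNA of neurofilaments, the structural proteins of thick axons, than other neurons of the same donors. NEFH was higher by 5.59 ± 1.11 log2 units (SE, n = 7 donors, adjusted p = 0.00449) and NEFL by 5.36 ± 1.06, at 13840 ± 18130 CPM (SD, TMM-scaled) against 108 ± 92.6. Without TMM scaling the level of NEFL in these nuclei ran from 109 to 31820 CPM by donor. The lowest was that of donor 5, with 109 against 30.2 CPM in other neurons and no PRPH UMI in 195 barcodes (up to 3 counts cannot be excluded). Urotensin 2 (UTS2), a peptide of motoneurons, was higher by 5.87 ± 0.85, and the type III filament gene PRPH by 7.09 ± 0.94. SLC5A7, the choline transporter that feeds acetylcholine synthesis, was higher by 4.30 ± 0.71. Other genes with large differences were S100A10 (5.87 ± 0.73), ANXA2 (5.57 ± 0.75), HSPB1 (5.29 ± 0.63), MT1X (5.01 ± 0.76) and LGALS1 (4.97 ± 0.65).

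Among genes of the upper range of expression that were lower in every donor were the synaptic vesicle gene SYNPR (-4.27 ± 0.54, SE), the transcription factor EBF3 (-3.92 ± 0.68), the vesicle calcium sensor SYT10 (-3.71 ± 0.47), the neuropeptide Y receptor NPY1R (-3.64 ± 0.50), the phosphatase PTPRT (-3.33 ± 0.57) and the acid-sensing channel ASIC2 (-3.02 ± 0.65). Of 11126 genes tested, 2597 passed (1527 higher, 1070 lower, 4380 unadjusted). The 2 sides held 1331 and 1822 nuclei, with sums of 116756 to 983884 UMIs against 1720514 to 9559711. Leaving out donor 2, 3 or 4 gave 1231, 1707 and 958 genes. Barcodes above 10000 UMIs left out gave 3954 (1864 higher, 2090 lower). Nuclei thinned to equal depth gave 1011 of 2752 tested. More genes were lower than higher also in barcodes of 2500 to 10000 UMIs alone (1098 higher, 2256 lower) and in those above 10000 alone (17 higher, 101 lower).

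Cytoskeletal genes were higher as a group: 13 of 19 were higher and none lower (13 and 0 adjusted over the list alone, camera adjusted p = 9.66e-11, adjusted p = 0.161 with an estimated correlation). NEFM was higher by 4.84 ± 1.11 (SE), TUBA1A by 3.13 ± 0.58, TUBB4A by 2.76 ± 0.46 and ACTB by 3.28 ± 0.53. Of 31 ALS genes 12 were higher and 1 lower (12 and 2 adjusted over the list alone, adjusted p = 0.000112, or 0.161 with an estimated correlation), among them PFN1 (3.65 ± 0.36), UBQLN2 (1.82 ± 0.35), ANXA11 (2.41 ± 0.47), SOD1 (2.91 ± 0.58), TUBA4A (3.08 ± 0.63) and STMN2 (2.23 ± 0.65). C9orf72 did not pass (0.41 ± 0.31, adjusted p = 0.343), nor did the synaptic gene SNAP25 (0.75 ± 0.50, adjusted p = 0.273). The themes of both lists are well known for motoneurons, so their direction is not independent evidence. Fold changes of this comparison also fell with genomic length (rho = -0.452 over all tested genes of known length). For genes at similar levels in other neurons, oligodendrocytes and astrocytes, the median was 0.722 under 19706 bp and -0.386 over 83559 bp. No list test of this comparison allowed for length, so whether either list rose beyond this shift was not tested.

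Housekeeping lists were higher in the same nuclei. The mitochondrial share of these nuclei was 0.784 ± 0.487% against 0.126 ± 0.0432% (SD) in other neurons. Among 5217 genes at similar levels in other neurons, oligodendrocytes and astrocytes, the fold change fell with genomic length (rho = -0.488). All 19 ribosomal protein genes were higher (RPL32 2.30 ± 0.28, RPS18 2.23 ± 0.27, 19 over the list alone, adjusted p = 4.12e-20, or 0.13 with an estimated correlation). Oxidative phosphorylation was higher in 14 of 15 genes (15 over the list alone, NDUFA1 2.29 ± 0.39, NDUFS5 2.42 ± 0.45, adjusted p = 2.43e-10, or 0.161 with an estimated correlation) and chaperones in 11 of 13 (12 over the list alone, CRYAB 2.69 ± 0.32, HSPA8 3.04 ± 0.53, adjusted p = 1.65e-09, or 0.161 with an estimated correlation). Cholesterol synthesis was higher in 7 of 15 (8 over the list alone, INSIG1 2.34 ± 0.38, SQLE 1.26 ± 0.26, adjusted p = 0.000112, or 0.139 with an estimated correlation) and immediate early genes in 3 of 9 (5 over the list alone, adjusted p = 0.0026, or 0.294 with an estimated correlation).

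Lists named for glia were higher in the same barcodes, and whether the RNA of their members came from glia was not tested. All 8 myelin genes were higher (8 over the list alone, MOBP 2.56 ± 0.35, MAG 2.77 ± 0.40, adjusted p = 6.26e-11, or 0.13 with an estimated correlation), as were 8 of 10 reactive astrocyte genes (10 over the list alone, AQP4 3.60 ± 0.28, GFAP 3.07 ± 0.28, adjusted p = 4.38e-18, or 0.014 with an estimated correlation). Activated microglia genes were higher in 5 of 6 (5 over the list alone, APOE 2.81 ± 0.26, SPP1 4.75 ± 0.79, adjusted p = 2.43e-10, or 0.0956 with an estimated correlation). Of markers, 8 of 8 for oligodendrocytes (median 2.44), 4 of 5 for microglia (1.77), 3 of 5 for astrocytes with 1 lower (2.40), and 2 of 2 for motoneurons (5.69) were higher, while 3 of 9 neuron markers were lower and none higher (-1.30). The 2 motoneuron markers tested were SLC5A7 and PRPH, since the low-count filter removed CHAT, ISL1, MNX1 and SLC18A3. Only the reactive astrocyte list kept its call with an estimated correlation.

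Several receptor and channel lists were lower in nuclei called motoneurons at the preset correlation, and none with an estimated one. Of the 1822 nuclei of other neurons 1102 were dorsal, so this comparison does not separate motoneurons from position in the cord. Fold changes of this comparison fell with genomic length (rho = -0.452 over all tested genes of known length), and the list tests made no allowance for length. Ionotropic glutamate receptors were lower in 11 of 16 genes (13 over the list alone, GRIN2B -1.65 ± 0.31, GRIN3A -1.73 ± 0.37, adjusted p = 9.8e-07, or 0.13 with an estimated correlation) and GABA and glycine receptors in 6 of 15 (7 over the list alone, GABRA4 -3.66 ± 0.57, GABRB2 -2.16 ± 0.40, adjusted p = 0.000115, or 0.13 with an estimated correlation). Calcium channels were lower in 8 of 10 (9 over the list alone, CACNA1E -2.33 ± 0.48, CACNA1G -1.84 ± 0.41, adjusted p = 0.0000166, or 0.13 with an estimated correlation). Against ventral neurons alone CACNA1G turned to 0.98 and did not pass (adjusted p = 0.0846). Of the other named motoneuron genes tested in that run, 43 were the same and 6 no longer passed. Potassium channels were lower in 8 of 18 and higher in 1 (10 and 1 over the list alone, adjusted p = 0.000124, or 0.161 with an estimated correlation): KCNH5 by -2.28 ± 0.40, KCND3 by -1.81 ± 0.33, and KCNA1 by 2.33 ± 0.55. Analgesic and nociceptive receptors were lower in 6 of 14 (7 lower and 1 higher over the list alone, GALR1 -2.75 ± 0.51, the opioid receptor OPRM1 -2.36 ± 0.55, adjusted p = 0.000817, or 0.13 with an estimated correlation). Dorsal horn transcription factors were lower in 7 of 10 and higher in 1 (8 and 1 over the list alone, EBF1 -2.89 ± 0.55, EBF2 -3.73 ± 0.80, adjusted p = 0.000124, or 0.13 with an estimated correlation).

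Neuropeptides split in nuclei called motoneurons: 3 of 12 were higher and 5 lower, the same over the list alone, with PDYN at -2.84 ± 0.47 and GAL at 2.86 ± 0.54 (list adjusted p = 0.199). Sodium channels gave 1 higher of 9 (3 higher and 3 lower over the list alone, adjusted p = 0.634), spastic paraplegia genes 2 of 14 (2 over the list alone, 0.205), ventral cord transcription factors 1 lower of 4 (1 over the list alone, 0.225), and local circuit factors 1 higher of 5 (1 over the list alone, 0.884). None of 3 long-range projection factors passed (0 over the list alone, adjusted p = 0.188). Perisynaptic astrocyte genes gave 2 higher and 1 lower of 10, the same over the list alone; their median (-0.38) and mean (-0.06) were negative while the test pointed up (adjusted p = 0.961). The lumbar HOX list had 2 genes tested and homeostatic microglia genes 1, too few for a list test.

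**Figure D3:**
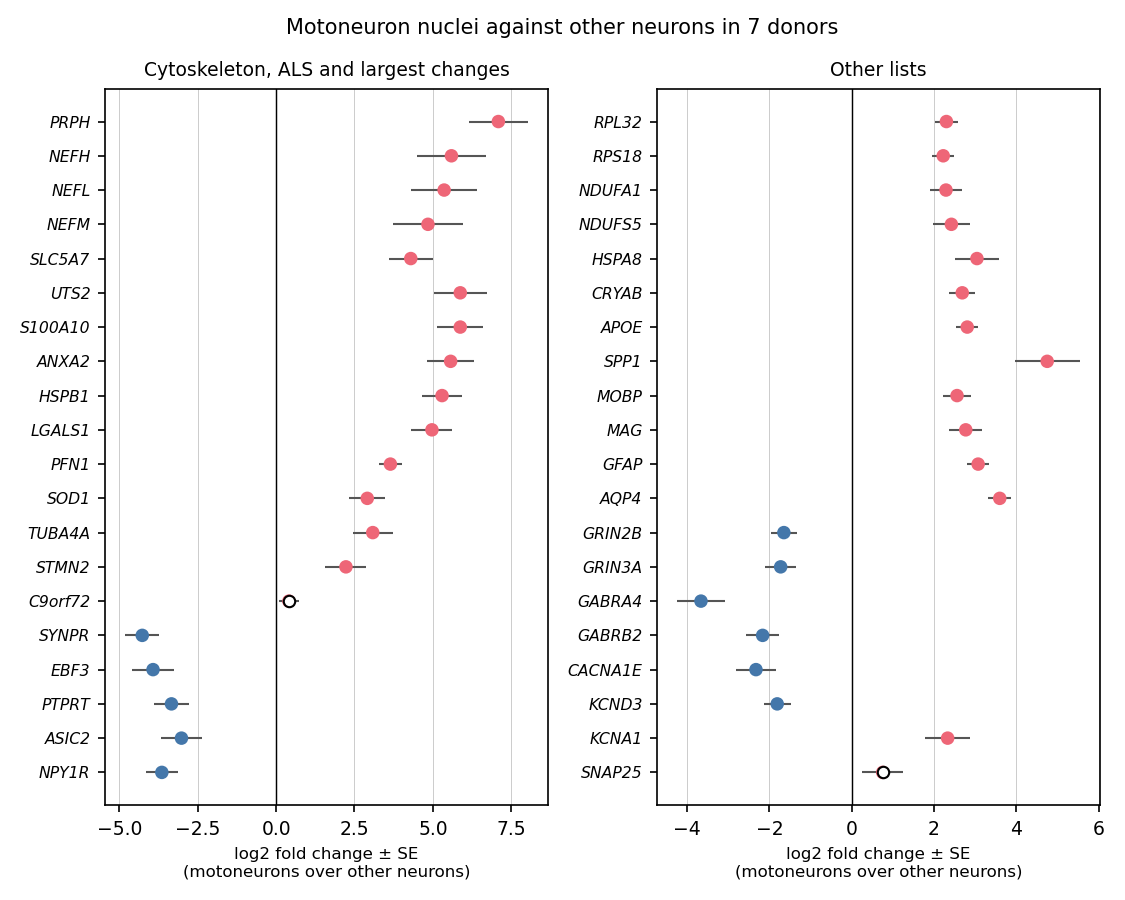
Log2 fold change ± SE of 40 genes, motoneurons against other neurons of the same donors (n = 7); red is higher, blue lower and white not passed. NEFH stood at 5.59 and SYNPR at -4.27.

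Excitatory neurons were set apart from inhibitory ones by transcription factors of the glutamatergic dorsal horn lineage. EBF2 was higher by 4.85 ± 0.15 (SE, n = 7), LMX1B by 3.94 ± 0.16 and DRGX by 3.29 ± 0.16. The peptide gene ADCYAP1 was higher by 4.50 ± 0.21, the calcium buffer CALB1 by 3.62 ± 0.20, the channel subunit CACNA2D1, the gabapentin target, by 3.25 ± 0.12 and the guidance cue SEMA3C by 3.24 ± 0.16. Inhibitory neurons carried GAD1, which makes GABA (-4.82 ± 0.14), the glycine transporter SLC6A5 (-3.71 ± 0.37), the lineage factors PAX2 (-4.31 ± 0.22) and PAX8 (-3.48 ± 0.20), the peptides NPPC (-3.64 ± 0.16) and PNOC (-3.51 ± 0.14), and CCBE1 (-3.63 ± 0.27). The glutamate transporter SLC17A6 was higher in excitatory neurons by 3.20 ± 0.17, and all 6 inhibitory markers were lower (median -4.01). Genes that define the 2 sides are circular here.

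Of 11773 genes tested between excitatory and inhibitory neurons, 2294 passed (1124 higher, 1170 lower, 3582 unadjusted, 972 against 783 nuclei). Dorsal horn transcription factors gave 8 higher and 4 lower of 12, the same over the list alone, with EBF1 at 2.13 ± 0.07 (adjusted p = 0.0365 with an estimated correlation). Ventral cord factors gave 3 lower of 5, the same over the list alone, with LHX1 at -4.27 ± 0.20 and LHX5 at -3.76 ± 0.31 (0.0426 with an estimated correlation). Of the 783 inhibitory nuclei 471 were dorsal, so this call does not show ventral position. Local circuit factors gave 5 lower of 6, the same over the list alone, with NFIB at -1.49 ± 0.11 and NEUROD2 at -3.26 ± 0.29 (adjusted p = 0.000108, or 0.179 with an estimated correlation). Long-range factors gave 3 higher of 4, the same over the list alone, with ZFHX4 at 1.08 ± 0.12 and ZFHX3 at 0.60 ± 0.17 (adjusted p = 0.0316, or 0.263 with an estimated correlation). Nuclei thinned to equal depth gave 656 of 3397 genes tested.

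Receptors and peptides also divided the transmitter classes. GABA and glycine receptors gave 7 higher and 3 lower of 15 in excitatory neurons (9 and 4 over the list alone, or 0.0426 with an estimated correlation), with GLRA3 at 1.08 ± 0.08, GLRA2 at 0.87 ± 0.07 and GABRA2 at 0.72 ± 0.06. Glutamate receptors gave 4 higher and 7 lower of 16, the same over the list alone (adjusted p = 0.0117, or 0.131 with an estimated correlation). The kainate receptors GRIK3 (-2.16 ± 0.07), GRIK1 (-1.56 ± 0.11) and GRIK2 (-1.35 ± 0.09) were higher in inhibitory neurons and GRID1 (1.19 ± 0.07) in excitatory ones. Neuropeptides gave 6 higher and 3 lower of 11, the same over the list alone, with TAC3 at 4.30 ± 0.23 and SST at 1.86 ± 0.16 (adjusted p = 0.00262, or 0.0642 with an estimated correlation). Calcium channels gave 5 higher and 2 lower of 10, the same over the list alone (adjusted p = 0.0117, or 0.179 with an estimated correlation), with CACNA2D3 at -1.99 ± 0.09.

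Some lists were mixed or flat between the transmitter classes. Analgesic and nociceptive receptors gave 4 higher and 3 lower of 14, the same over the list alone (adjusted p = 0.391). NPY1R 2.27 ± 0.10 and ADRA2A 1.07 ± 0.23 were higher in excitatory neurons, SSTR2 lower (-1.98 ± 0.13). ALS genes gave 1 higher and 3 lower of 29, the same over the list alone, with ERBB4 at 1.27 ± 0.06 and SOD1 at -0.33 ± 0.09; the median (-0.04) and mean (-0.01) were negative and the test pointed up (adjusted p = 0.979). Potassium channels gave 4 higher, with KCNN3 at 0.90 ± 0.08, and 3 lower of 18 (4 and 5 over the list alone, adjusted p = 0.88); their median (-0.05) and mean (0.02) differed in sign. None of 19 ribosomal protein genes and none of 8 myelin genes passed (0 of each over the list alone).

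Dorsal neurons differed from mid and ventral ones of the same transmitter class in 3833 genes. The natriuretic peptide NPPC was higher dorsally by 4.58 ± 0.21 (SE, n = 7 donors, 28 sums), TSPAN18 by 3.15 ± 0.23, EBF2 by 2.91 ± 0.51, the nuclear receptor RORB by 2.85 ± 0.38, the kinase STK32A by 2.85 ± 0.16 and HPSE2 by 2.75 ± 0.27. Lower dorsally were NELL1 (-3.14 ± 0.21), the serotonin receptor HTR2C (-2.41 ± 0.18), the RNA-binding ELAVL4 (-2.40 ± 0.15), the factor MEIS2 (-2.31 ± 0.23) and the adhesion gene CNTN5 (-2.18 ± 0.23). Of 9945 genes tested, 3833 passed (1863 higher, 1970 lower, 4585 unadjusted, 1102 against 653 nuclei). Dorsal nuclei thinned to equal depth with the ventral ones gave 399 of 1432 genes tested.

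Transcription factors and calcium channels followed position. Dorsal horn factors were higher in 6 of 7 genes, the same over the list alone, with EBF1 at 2.49 ± 0.13 and DRGX at 2.14 ± 0.26 (adjusted p = 0.0363 with an estimated correlation); the authors' region names may rest on such genes. Calcium channels were higher in 5 of 9 (6 over the list alone, or 0.00043 with an estimated correlation), with the low-threshold channel CACNA1G at 2.60 ± 0.14 and CACNA1E at 1.07 ± 0.13. Ventral cord factors were lower in 3 of 4 (3 lower and 1 higher over the list alone), with FOXP2 at -2.04 ± 0.35 (adjusted p = 0.0192, or 0.0651 with an estimated correlation). Local circuit factors were lower in 4 of 5 (5 over the list alone, adjusted p = 0.00487, or 0.204 with an estimated correlation), with NFIA at -1.56 ± 0.16 and TCF4 at -1.06 ± 0.18. Long-range factors split, with ZFHX3 at -1.51 ± 0.15 and ZFHX4 at 0.61 ± 0.14 (1 higher and 2 lower of 3, also over the list alone, adjusted p = 0.183).

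Cholesterol synthesis was lower dorsally in 13 of 14 genes, the same over the list alone, with INSIG1 at -1.01 ± 0.14 (adjusted p = 6.55e-07, or 0.0651 with an estimated correlation). Cytoskeletal genes were lower in 12 of 18 (12 lower and 1 higher over the list alone, adjusted p = 0.0000879, or 0.201 with an estimated correlation), with SPTAN1 at -0.74 ± 0.06, DYNC1H1 at -0.47 ± 0.06 and TUBA4A at -0.90 ± 0.15. Oxidative phosphorylation was lower in 8 of 15 (9 over the list alone, adjusted p = 0.0258, or 0.273 with an estimated correlation). Of 27 ALS genes 11 were lower and 2 higher (12 and 2 over the list alone, adjusted p = 0.0944), among them KIF5A (-0.52 ± 0.09), NEK1 (-0.31 ± 0.06) and C9orf72 (-0.57 ± 0.10). Ribosomal protein genes were higher dorsally in 6 of 19 (5 over the list alone, adjusted p = 0.0361, or 0.353 with an estimated correlation).

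Myelin genes were higher dorsally in 5 of 6, the same over the list alone, with MOG at 0.65 ± 0.16 (adjusted p = 0.0168, or 0.204 with an estimated correlation), beside 6 of 7 oligodendrocyte and 3 of 3 microglia markers. Median UMIs per subtype ran from 5476 to 19603 dorsally and from 13490 to 37756 in mid and ventral subtypes. Whether glial RNA in the droplets accounts for these glial genes was not tested. Potassium channels split in dorsal neurons: 8 were higher and 5 lower of 18 (10 and 6 over the list alone, adjusted p = 0.148), with KCND3 at 1.41 ± 0.13, KCNQ5 at 1.45 ± 0.18 and KCNA1 at -1.54 ± 0.19. Sodium channel subunits gave 2 higher and 5 lower of 9, the same over the list alone (adjusted p = 0.0899), with SCN3B at 1.16 ± 0.12 and SCN4B at -1.35 ± 0.15. Analgesic and nociceptive receptors gave 6 higher and 3 lower of 10, the same over the list alone (adjusted p = 0.504). OPRM1 0.90 ± 0.14 and GALR1 1.87 ± 0.20 were higher, and the substance P receptor TACR1 was lower (-1.26 ± 0.15). The peptide genes PNOC (2.20 ± 0.26) and SST (1.85 ± 0.47) were higher dorsally, PDYN did not pass (1.31 ± 0.80, adjusted p = 0.205), and 2 of 10 neuropeptides passed (2 over the list alone, adjusted p = 0.261). GRIN2A was higher (1.21 ± 0.12) and GRIK4 lower (-0.98 ± 0.09) in a glutamate receptor list of 6 higher and 5 lower of 16, the same over the list alone (adjusted p = 0.393).

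**Figure D4:**
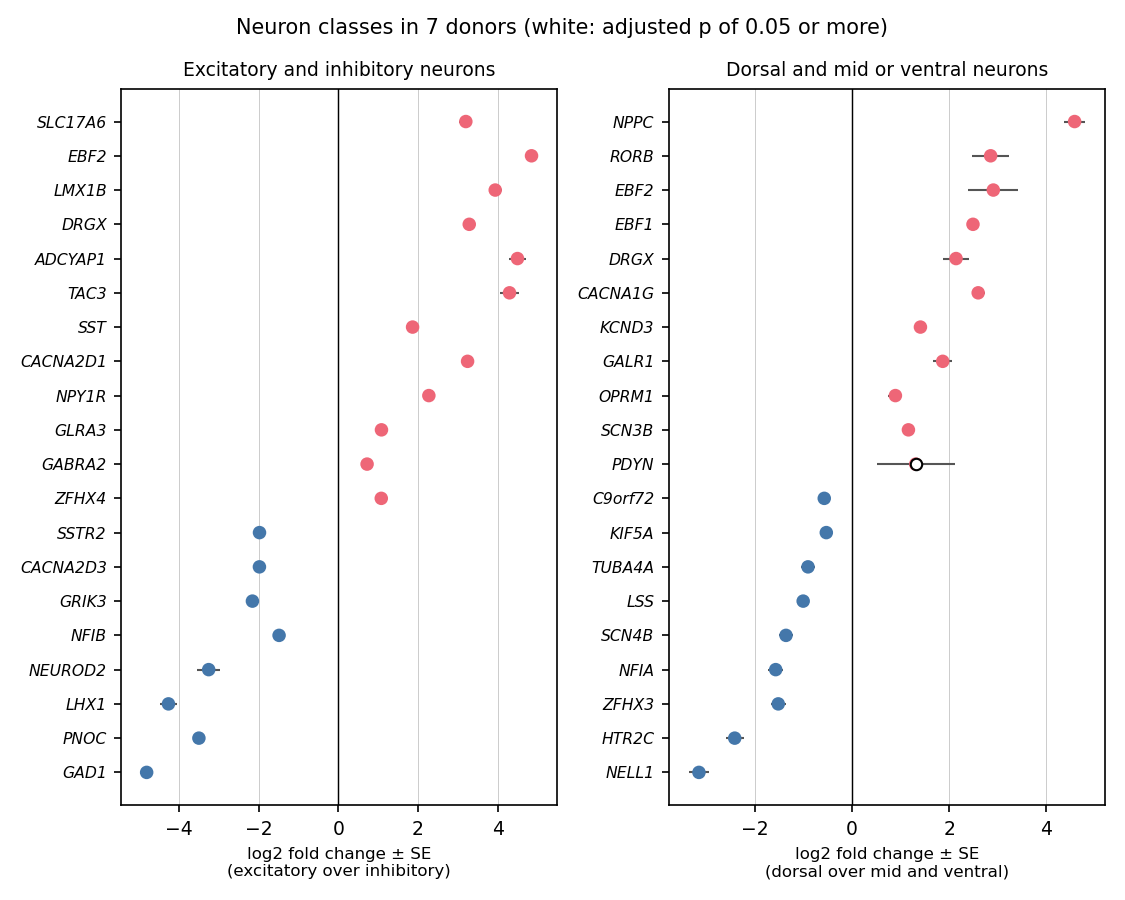
Log2 fold change ± SE of 20 genes each for excitatory against inhibitory neurons and for dorsal against mid and ventral neurons (n = 7); red is higher, blue lower, white not passed. GAD1 stood at -4.82 and NPPC at 4.58 respectively.

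The 2 largest oligodendrocyte subtypes, Oligo-4 and Oligo-5, differed in 3358 genes. Oligo-4 held more of the scaffold gene KANK4 (2.64 ± 0.21, SE, n = 7), the lipase LIPC (2.62 ± 0.20), the proton pump subunit ATP6V0D2 (2.29 ± 0.13) and the inositol transporter SLC5A11 (1.79 ± 0.13). Oligo-5 held more of the phosphatase PTPRM (-2.32 ± 0.30), the membrane repair gene DYSF (-2.29 ± 0.17), the laminin LAMA2 (-1.95 ± 0.14) and the guanylate cyclase subunit GUCY1A2 (-1.79 ± 0.12). Of 12343 genes tested, 3358 passed (1525 higher, 1833 lower in Oligo-4, 4644 unadjusted, 9908 against 7236 nuclei). If the authors drew the subtypes from the same counts, counts of subtype genes are circular. Nuclei thinned to equal depth gave 1785 of 9815 genes.

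Ribosomal protein genes were lower in Oligo-4 in 18 of 19 (19 over the list alone, adjusted p = 0.0163 with an estimated correlation), with RPLP1 at -0.56 ± 0.06 and RPS27A at -0.59 ± 0.07. Reactive astrocyte genes were lower in 7 of 10 (8 lower and 1 higher over the list alone, or 0.0245 with an estimated correlation), with GFAP at -0.74 ± 0.06 and AQP4 at -0.75 ± 0.08, and activated microglia genes in 8 of 10 (9 over the list alone, adjusted p = 5.79e-06, or 0.087 with an estimated correlation), with APOE at -0.80 ± 0.07, CD9 at -0.78 ± 0.08 and HLA-DRA at -0.81 ± 0.09. Markers of astrocytes (4 of 7), microglia (5 of 7), neurons (4 of 9, 1 higher) and OPC (3 of 5) were lower too, and whether Oligo-5 itself expressed these genes was not tested. Oligo-5 nuclei were shallower in every donor. In donor 4, for example, 633 of 1888 held under 2000 UMIs, against 84 of 2711 Oligo-4 nuclei. Oxidative phosphorylation was lower in Oligo-4 in 8 of 15 (10 over the list alone, COX7C -0.41 ± 0.08, adjusted p = 0.00371, or 0.218 with an estimated correlation) and immediate early genes in 4 of 9 (6 over the list alone, FOS -1.04 ± 0.13, adjusted p = 0.0138, or 0.114 with an estimated correlation).

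Myelin genes split between the oligodendrocyte subtypes: MBP (0.36 ± 0.09) and UGT8 (0.40 ± 0.07) were higher in Oligo-4 and OPALIN lower (-0.37 ± 0.09), 3 higher and 1 lower of 11 (5 and 1 over the list alone, adjusted p = 0.0881). Cholesterol synthesis was higher in 5 of 15, the same over the list alone, with LSS at 0.45 ± 0.08 and SQLE at 0.42 ± 0.08 (adjusted p = 0.00169, or 0.466 with an estimated correlation). Potassium channels were lower in 8 of 16 and higher in 1, the same over the list alone (KCND2 -0.71 ± 0.08, adjusted p = 0.0117, or 0.385 with an estimated correlation), sodium channels in 3 of 6 (5 over the list alone, SCN1A -0.79 ± 0.10, adjusted p = 0.00805, or 0.187 with an estimated correlation) and analgesic receptors in 3 of 6 (4 over the list alone, NTRK2 -1.14 ± 0.08, adjusted p = 0.0101, or 0.114 with an estimated correlation). Dorsal horn factors, mostly neuronal genes, were lower in 5 of 7, the same over the list alone (adjusted p = 0.0124, or 0.114 with an estimated correlation). GRIA2 was higher (1.03 ± 0.14) and GRIK3 lower (-1.65 ± 0.12), while NEFH was lower (-0.61 ± 0.08) and KIF5C higher (0.81 ± 0.07) within mixed glutamate receptor and cytoskeleton lists.

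Microglia-3 and Microglia-1, the largest microglia subtypes, differed in 947 genes. Microglia-3 held more of the haemoglobin scavenger receptor CD163 (3.09 ± 0.25, SE, n = 6), the transglutaminase F13A1 (2.55 ± 0.23), EYA2 (2.40 ± 0.22), the zinc transporter TMEM163 (1.88 ± 0.22) and TPRG1 (1.86 ± 0.17). It held less of RASGEF1C (-1.87 ± 0.11), PRDM11 (-1.77 ± 0.14), the plasminogen activator PLAT (-1.53 ± 0.12), and of the surveillance receptors P2RY12 (-1.42 ± 0.10), P2RY13 (-1.36 ± 0.15) and CX3CR1 (-1.35 ± 0.10). Of 10335 genes tested, 947 passed (482 higher, 465 lower, 2112 unadjusted, 3583 against 1875 nuclei). Nuclei thinned to equal depth gave 552 of 6886 genes and DESeq2 gave 602, and subtype-defining genes are circular.

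Homeostatic microglia genes were lower in Microglia-3 in 9 of 9 (9 over the list alone, adjusted p = 1.23e-26, or 0.0193 with an estimated correlation), including the growth factor receptor CSF1R (-0.54 ± 0.07). Activated microglia genes were mixed: 3 were higher and 2 lower of 14 (3 and 3 over the list alone, adjusted p = 0.478), with GPNMB at 1.42 ± 0.18, SPP1 at 0.76 ± 0.07, APOE at 0.42 ± 0.10 and ITGAX at -0.51 ± 0.10; the list median (-0.10) and mean (0.01) differed in sign. Immediate early genes were lower in 3 of 9 (5 lower and 1 higher over the list alone, adjusted p = 0.0349, or 0.732 with an estimated correlation): EGR1 -0.75 ± 0.12, EGR3 -1.24 ± 0.21 and IER2 -0.69 ± 0.14. Ventral cord factors were lower in 2 of 3, the same over the list alone, with FOXP2 at -0.75 ± 0.10 and TAL1 at -0.90 ± 0.12 (adjusted p = 0.00147, or 0.135 with an estimated correlation). Perisynaptic astrocyte genes were higher in 3 of 9 (4 over the list alone, adjusted p = 0.00469, or 0.504 with an estimated correlation), with GLUL at 0.85 ± 0.09 and SLC1A3 at 0.25 ± 0.07. OPRM1 (-0.63 ± 0.11) and CACNA1A (-0.76 ± 0.15) were lower and KCNMA1 was higher (0.47 ± 0.07).

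White matter (WM) astrocytes differed from the largest grey matter subtype, GM Astrocytes-2, in 3120 genes. WM astrocytes held more of CCDC85A (4.12 ± 0.40, SE, n = 7), SBSPON (4.10 ± 0.20), the chitinase-like CHI3L2 (3.84 ± 0.34), the membrane repair gene MYOF (3.80 ± 0.23), the kinase MUSK (3.78 ± 0.26) and NRXN3 (3.60 ± 0.37). They held less of CABLES1 (-4.88 ± 0.39), UNC13C (-3.73 ± 0.28), IGSF21 (-3.55 ± 0.20) and RIMS1 (-3.29 ± 0.26). Of 11871 genes tested, 3120 passed (1550 higher, 1570 lower, 4314 unadjusted, 3651 against 2663 nuclei). Nuclei thinned to equal depth gave 1675 of 6781 genes, and subtype genes are circular.

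Perisynaptic genes, whose products clear glutamate and GABA at synapses, were lower in WM astrocytes in 9 of 11, the same over the list alone (adjusted p = 0.0292 with an estimated correlation): SLC6A11 -3.28 ± 0.26, SLC1A2 -2.23 ± 0.14, GPC5 -1.87 ± 0.15 and MERTK -1.40 ± 0.09. Reactive astrocyte genes were higher in 9 of 10, the same over the list alone, with VIM at 1.95 ± 0.19, CD44 at 1.33 ± 0.18 and MAOB at 1.20 ± 0.16 (adjusted p = 0.0000383, or 0.258 with an estimated correlation). Immediate early genes were higher in 5 of 9, the same over the list alone, with DUSP1 at 1.13 ± 0.16 and IER2 at 0.83 ± 0.16 (adjusted p = 0.0201, or 0.548 with an estimated correlation). Cytoskeletal genes were higher in 5 of 17, the same over the list alone, with TUBA1A at 1.13 ± 0.14 and ACTB at 0.65 ± 0.10 (adjusted p = 0.0485, or 0.258 with an estimated correlation). Ribosomal protein genes were higher in 4 of 19 (9 over the list alone, RPL37A 0.52 ± 0.13, adjusted p = 0.0414, or 0.258 with an estimated correlation). Ventral cord factors were lower in 3 of 4, the same over the list alone, with FOXP2 at -0.82 ± 0.21 (adjusted p = 0.0035, or 0.258 with an estimated correlation).

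GRIN2A (2.14 ± 0.27) and GRIA3 (1.48 ± 0.13) were higher and GRIA2 lower (-1.51 ± 0.13) in WM astrocytes, 6 higher and 5 lower of 15, the same over the list alone (adjusted p = 0.745). KCNH1 was higher (3.55 ± 0.36) and KCND2 lower (-1.47 ± 0.10) in a potassium channel list of 4 higher and 6 lower of 14 (4 and 7 over the list alone, adjusted p = 0.22) whose median was -0.24 and mean 0.01. Calcium channels gave 2 higher and 5 lower of 8, the same over the list alone (adjusted p = 0.0565), with CACNA1B at -1.82 ± 0.18 and CACNA1D at -1.51 ± 0.13. ALS genes gave 2 higher and 5 lower of 30, the same over the list alone (adjusted p = 0.745), with ANXA11 at 1.92 ± 0.17, C9orf72 at 0.61 ± 0.12 and ERBB4 at -0.80 ± 0.10. Chaperones gave 3 higher of 14 (5 over the list alone, adjusted p = 0.119), with HSPB1 at 1.27 ± 0.20 and CRYAB at 0.69 ± 0.12.

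**Figure D5:**
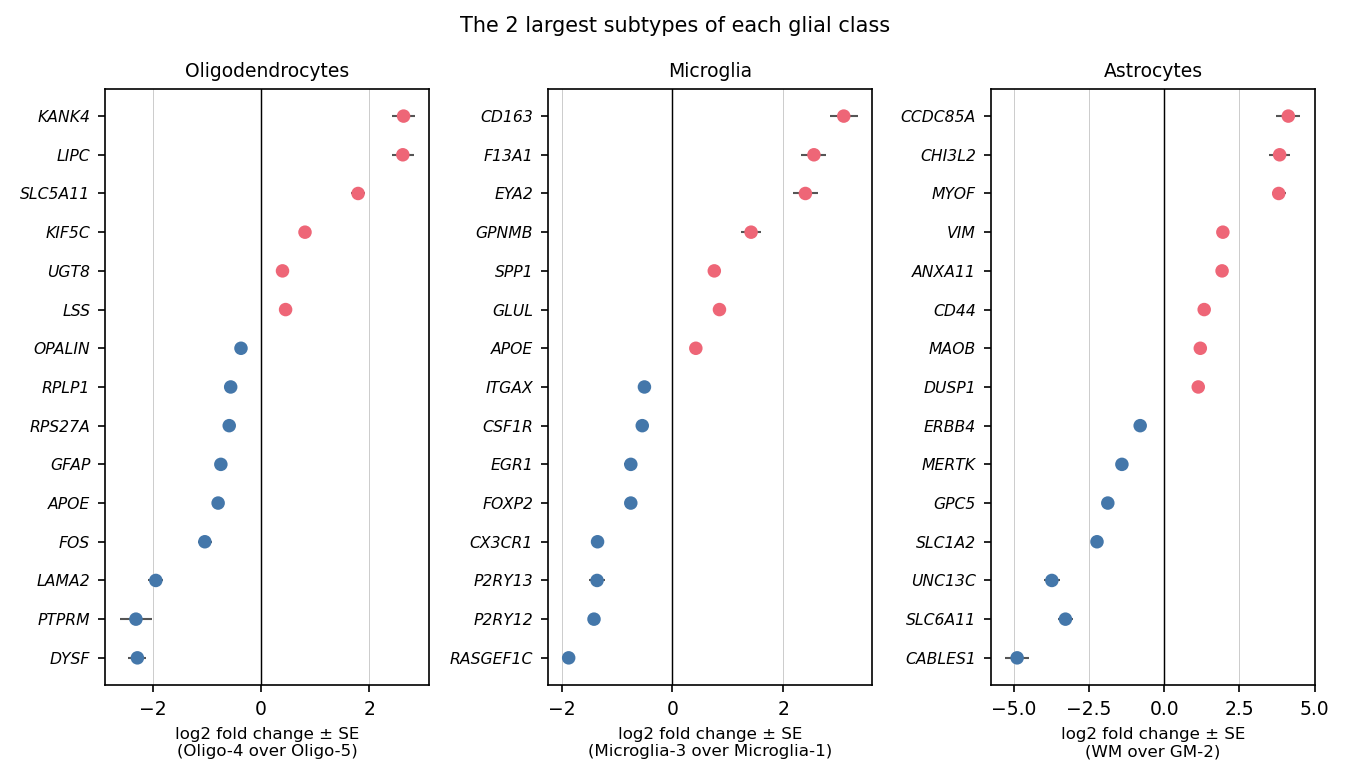
Log2 fold change ± SE of 15 genes each for Oligo-4 against Oligo-5 (n = 7), Microglia-3 against Microglia-1 (n = 6) and WM against GM Astrocytes-2 (n = 7); red is higher, blue lower, white not passed. KANK4 stood at 2.64, CD163 at 3.09 and CABLES1 at -4.88.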

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

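Of 276 sets of donor values tested with the Dixon rule 24 held a value that stood apart, where about 1 in 20 would by chance. The tests of glial RNA and of motoneuron markers below were chosen after the result was seen; those of gene length and depth were written before.

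The nuclei called motoneurons are low in UMIs and rich in neurofilament RNA. Among 5217 genes at similar levels in other neurons, oligodendrocytes and astrocytes, the fold change fell with genomic length (rho = -0.488; 6 of 7 donors negative), which is consistent with cytoplasmic RNA in part of these barcodes. After thinning, the median log2 fold change of NEFL, NEFM and NEFH was 6.72. Random thinning keeps each gene's expected share of the UMIs, so this test could not decide on lower depth as the cause. These barcodes were compared with glial nuclei, so RNA of glial cytoplasm was not measured. RNA of glial nuclei as the source of the barcodes' neurofilament RNA is excluded for all donors pooled. The highest pooled glial level (Schwann cells) was 0.398% of that in these barcodes. Within donors that share was at most 6.43% in 6 of 7 but 18.6% in donor 5, whose few neurofilament UMIs leave it open there, and other glial RNA in the droplets is not excluded. RNA of motoneurons could not be told: without the low-count filter 3 of 5 markers passed (SLC5A7 4.19, PRPH 7.02, MNX1 5.001). ISL1 (2.20, adjusted p = 0.0559) and CHAT (1.51, adjusted p = 0.159) did not. The listed marker SLC18A3 held 0 UMIs on both sides and was not counted. The 22 barcodes above 10000 UMIs held NEFL at 746 CPM, pooled, and the 1170 up to 2500 UMIs at 18890 CPM.

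In motoneurons against other neurons the value that stood apart, in a donor that differed by gene, was a log2 difference of -2.81 for PRPH (others 4.95 to 9.43), -1.96 for C9orf72 (0.20 to 0.94), -8.68 for GABRB2 (-3.18 to -0.82), -3.70 for GAL (1.90 to 5.53) and 0.25 for SQLE (1.14 to 1.73). PRPH had 0 UMIs in 195 barcodes of 1 donor, where up to 3 counts cannot be excluded. In excitatory against inhibitory neurons the values were 8.74 for ADCYAP1 (3.53 to 5.48), -1.66 for PNOC (-4.09 to -3.09), -6.47 for PAX8 (-4.29 to -2.67) and -7.83 for LHX1 (-5.38 to -3.57). In dorsal neurons they were 2.60 for DRGX (1.16 to 1.72), 5.03 for CACNA1G (2.13 to 3.18), -2.83 for TACR1 (-1.53 to -0.64), -1.55 for C9orf72 (-0.54 to 0.20), -0.43 for PNOC (1.58 to 3.03) and 1.77 for GRIN2A (1.05 to 1.28). In WM astrocytes they were 5.79 for SBSPON (3.07 to 4.18), -3.12 for SLC1A2 (-2.31 to -1.90) and 0.10 for ACTB (0.59 to 0.96). The oligodendrocyte and microglia comparisons had none.

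The meningeal share was 6.96% (others 0.254 to 1.83) and the Schwann cell share 1.52% (0.0314 to 0.426) in the same donor, as if more membrane and root had been taken, which was not tested. The lymphocyte share was 0.958% (0.191 to 0.458) in 1 donor. The log2 median of OPC was 11.60 (12.40 to 12.94), and the mitochondrial percent of meningeal cells was 1.36 (0.219 to 0.694). Nuclei numbered 15048 (5155 to 8354) in donor 4, whose barcodes came from 2 libraries; whether that number is the one of the sample titles is open.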

How the results depend on the processing

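Of 344 alternative values 293 stayed on the same side of their test, within 1.5 times for a count or within 1 SD for a share. Of the others 26 counts moved by more than 1.5 times, 9 became stronger, 6 weaker and 10 turned, and of 3918 values for named genes 3790 were the same, 2 stronger, 122 weaker and 4 turned. The splits of motoneuron barcodes by UMIs, the libraries of donor 4 and the neurons without motoneurons were chosen after the data were seen; the others were written before. Both alternatives for the sample titled 6A (left out, own replicate) were not run, since no nucleus carries that name. The cause was not tested for any changed result.

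Without the donor block (no replicate block), the counts of genes were 822 for excitatory against inhibitory neurons, 2413 for dorsal neurons, 126 for oligodendrocytes, 2 for microglia and 978 for astrocytes, while 3590 motoneuron genes and 252 class genes stayed within 1.5 times. Without it 21 of 29 named genes no longer passed for oligodendrocytes, 26 of 27 for microglia, 9 of 36 for astrocytes, 2 of 38 for excitatory and 1 of 46 for dorsal neurons. Thinned nuclei gave 1011, 656, 399, 1785, 552 and 1675 genes in the order motoneurons, excitatory, dorsal, oligodendrocytes, microglia and astrocytes, with fewer genes tested. DESeq2 gave 602 for microglia. Motoneurons without barcodes above 10000 UMIs gave 3954 genes, those barcodes alone 118, and runs without donor 2, 3 or 4 gave 1231, 1707 and 958. In the barcodes above 10000 UMIs alone 18 named genes were the same, 33 no longer passed and 3 turned. Those barcodes numbered 22, and only donors with at least 3 of them entered that run. Leaving out 1 donor gave 958 to 2922 genes for motoneurons, 1777 to 2228 for excitatory, 3102 to 3700 for dorsal, 2619 to 3134 for oligodendrocytes, 641 to 997 for microglia, 2534 to 3091 for astrocytes and 251 to 270 for classes. Barcodes of 2500 to 10000 UMIs gave 32.7% of genes higher against 58.8%, and those above 10000 left out 47.1%.

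Lists that passed camera numbered 16, 8, 9, 10, 4 and 6 in the same order, and 1, 3, 2, 2, 1 and 1 with an estimated correlation. With fry dorsal neurons had 20, oligodendrocytes 17 and astrocytes 14. The log2 change turned for CACNA1G (0.98, adjusted p = 0.0846, ventral neurons only) and, in barcodes above 10000 UMIs alone, for MT1X (-0.00221), C9orf72 (-0.14) and MOBP (-0.39). None of these 3 passed there (adjusted p = 0.9997, 0.978 and 0.966).

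Neurons minus astrocytes in log2 median UMIs ran from -0.0402 to 0.65 with 1 donor left out, minus OPC from -0.18 to 0.39, minus endothelial cells from -0.0829 to 0.46 and minus ependymal cells from -0.13 to 0.51. By genes detected the ependymal difference was -0.0585. By mean UMIs neurons exceeded oligodendrocytes by 1.32, microglia by 1.88, astrocytes by 1.10, OPC by 0.93, meningeal cells by 1.19, endothelial cells by 0.88, lymphocytes by 2.40 and ependymal cells by 0.98, and motoneurons minus other neurons stood at -2.84, with adjusted exact p of 0.0246 or 0.0382. The excitatory minus inhibitory share ran from 4.72 to 6.85 points, with an exact p of 0.0625 in 6 runs and 0.0313 without donor 7. Without donor 6 the meningeal share was 0.929% and the Schwann cell share 0.188%, within 1 SD of the mean over all donors but over 1.5 times lower.

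Class names were also exchanged within donors. If the authors drew the names from the same counts, an exchange lowers the number of genes by design, so the splits do not show whether chance can be excluded. The real arrangement was the only 1 of 64 with as many genes for motoneurons (2597, highest other 452), excitatory neurons (2294, 146), dorsal neurons (3833, 2467), oligodendrocytes (3358, 656) and astrocytes (3120, 542), of 32 for microglia (947, 357) and of 30 for classes (264, 59). The high dorsal values had 1 donor exchanged.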

Other observations

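Values of whole classes and of glial neurofilament UMIs are given here. The tests of ratios to NEFL and the correlations 0.43 and 0.921 were chosen after the result was seen, and the rho for free RNA was written before.

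Receptor genes of neurons were also high in OPC: ionotropic glutamate receptors in 13 of 16 genes (adjusted p = 0.0000722 with an estimated correlation; GRIA2 3.75 ± 0.19), potassium channels in 12 of 18 (0.0101) and calcium channels in 7 of 10 (0.00926). The opioid receptor OPRM1 was higher than the mean of other classes in microglia (4.18 ± 0.20; 264 ± 226 CPM) and in neurons (4.01 ± 0.20). C9orf72 was higher in microglia (1.34 ± 0.11) and oligodendrocytes (0.71 ± 0.12), and ERBB4 in astrocytes (2.50 ± 0.23) and OPC (2.36 ± 0.22). Oligodendrocytes held all 11 myelin genes (0.0212) and 10 of 14 spastic paraplegia genes with 1 lower (0.0292) at higher levels. Astrocytes held 10 of 12 perisynaptic genes with 1 lower (0.00653) and 7 of 10 reactive genes with 1 lower (0.00433), and APOE stood higher in microglia (2.94 ± 0.15) and astrocytes (2.28 ± 0.15). Microglia held 14 of 15 activated (0.0211) and 9 of 9 homeostatic genes (0.0401). Lymphocytes held 4 of 5 local circuit factors at lower levels (0.0138). HOXA9 was higher in astrocytes (1.43 ± 0.23) as in neurons (1.73 ± 0.22).

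Neurofilament UMIs also stood in glial nuclei, with NEFL at 50.0 CPM, pooled over donors, in oligodendrocytes, 75.1 in microglia and 40.2 in astrocytes. Free RNA of the neurofilament-rich barcodes could not be told, with rho = 0.5 over donors between their share and the oligodendrocyte level (exact p = 0.267). The correlation was 0.43 (exact p = 0.357) over 7 donors and 0.921 (exact p = 0.0333) over the 5 left without the 2 whose share lay farthest from the median. Nuclear expression of NEFM, NEFH and STMN2 was left open too: their ratios to NEFL differed by at most 1.2-fold between oligodendrocytes, microglia and astrocytes within donors, and a similar ratio does not exclude expression beside NEFL. The bounds for these ratios were set after the result was seen. For PRPH the ratio differed by 2.12-fold between microglia and astrocytes, and by 1.77-fold without donor 7, so nuclear expression of PRPH in glia could not be told from the other sources.

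Mitochondrial RNA was highest in lymphocytes (1.41%) and ependymal cells (1.37%), and stood at 0.784 ± 0.487% in nuclei called motoneurons against 0.126 ± 0.0432% in other neurons (SD).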
